A study of Mus musculus with 2 samples.

How the data were processed

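Long reads were measured in 2 libraries of adrenal gland from 14-day-old male B6CASTF1/J mice, which the labels describe as biological replicates 1 and 2 of a single experiment. Per the file headers and the accompanying description, the reads were aligned to mm10 and assigned to transcript models with the GENCODE M21 annotation. The source column of the deposited annotation names TALON, which groups long reads by their intron chain and classes each chain against the annotation. The aligner, the TALON version and any filter on the models are not given in the sources used here. The deposited values are read counts per transcript model, whole numbers with no normalization by the authors, listed for models with at least 1 read, with 1 table per library and no pooling of replicates. The deposited tables also give, per the file headers, the number of exons, the length and the class of each model: known, incomplete splice match (part of an annotated chain), new in catalog (annotated splice sites in a new combination), new not in catalog (an unannotated splice site), genomic, antisense or intergenic. Incomplete splice matches are called truncated below, although the class alone does not show that a molecule was cut short. Exon coordinates came from the deposited annotation of each library.

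Counts were summed over all models of each annotated gene. All 18177 genes with reads were found in the reference annotation by identifier, with the same symbol, start and end. ERCC spike-ins (1.72% and 1.79% of reads) were kept out of library sizes and used as a technical comparison. The labels also name longer synthetic spike-ins of another set, which were not analysed here. CPM (counts scaled to a total of 1000000) were computed from the reads without spike-ins, 964815 in replicate 1 and 985101 in replicate 2, and reads in unannotated genes (4.59% and 5.24%) stayed in the denominator. Listed models numbered 112323 and 112820, of which 62.1% and 61.7% had a single read.

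With 1 group of 2 replicates there is no contrast between conditions, so levels are given as mean and SD (n = 2) and all tests compare the libraries. Each gene with at least 10 reads over both libraries was tested with a two-sided exact binomial test of its reads in replicate 2 against the share of all reads in replicate 2, with Benjamini-Hochberg adjustment and a threshold of 0.05. Intervals of ratios of single genes are exact Clopper-Pearson intervals, those of shares are Wilson intervals, both at 95%. Bootstrap intervals are named where they occur. A count of 0 was set to 3 reads per library for a lower bound of a ratio. Reads are not marked with molecular identifiers in the deposited counts, so the intervals and bounds of single genes cover counting error only.

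Gene lists fixed before the data were examined covered steroidogenesis, the zona glomerulosa, the zona fasciculata, the X-zone, cholesterol synthesis, chromaffin cells, neurons, Schwann cells, capsule and fibroblasts, smooth muscle and pericytes, endothelium, macrophages and immune cells, erythroid cells, adipose tissue, kidney, liver, the cell cycle, immediate early and stress genes, imprinted genes, mitochondrially encoded genes, sex chromosome genes and genes chosen for their isoforms. For each list the median log2 ratio, with 0.5 reads added to each library, was placed among 10000 random lists of the same size matched on mean expression, which describes these libraries only. The number of calls is given over all genes tested and adjusted over the list alone.

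Isoforms were compared by exact intron chain, matched between libraries by chromosome, strand and coordinates. Known models, single-exon ones included, and new in catalog and new not in catalog chains counted as full-splice reads, and a chain classed as truncated in either table was left out. Genes with at least 20 full-splice reads in each library were described, and those with more than a single transcript were tested with a two-sided Fisher's exact test of the top transcript against all others, with the same adjustment.

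Also before the data were examined, the groups, the tests, the alternatives and the rule for named genes were fixed. The rule took the 10 genes with the highest mean CPM, all members of the steroidogenesis and chromaffin lists, the 4 highest of each other list and any list member past the threshold. It also took the 10 largest ratios in each direction, ranked with 0.5 reads added to each library, among called genes with at least 50 reads, up to 12 isoform genes with a second transcript of at least 10%, the 5 largest differences in isoform share and the 10 unannotated chains with the most reads. Later additions are named where they occur.

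The tests were tested on simulated data. For the binomial test, counts were drawn from the real means and library sizes. The 200 changed genes were taken only from genes with at least 50 reads over both libraries. The test recovered 20.5% of 1.5-fold, 63.0% of 2-fold and 94.0% of 4-fold changes, with 0, 3 and 4 false calls among 10724, 10730 and 10711 genes. For the isoform test on 4817 genes, shifts were placed only in genes with more full-splice reads over both libraries than the test required. It recovered 69.5% of shifts of 20 points and 98.5% of shifts of 40 points. Recovery in tested genes of fewer reads was not measured. These figures rest on counting error alone.

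Alternatives were edgeR TMM factors and DESeq2 median-of-ratios factors as other scalings (1.055 and 0.948, and 1.045 and 0.957 for replicates 1 and 2), other read minimums, reads of known models only, no mitochondrially encoded genes, truncated models counted as transcripts, other pseudocounts and leaving out each replicate. The tools edgeR and DESeq2 gave scaling factors only, since their tests need a contrast. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.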

Results

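Long-read RNA sequencing, in which each read can span a whole transcript, was performed on adrenal glands of 14-day-old male F1 hybrid mice (B6CASTF1/J). The series held 1 group with 2 biological replicates. The sample labels name a set of 3 males without stating how many animals entered each library. Both libraries carry the same donor identifier, while their biosample labels are numbered 3 and 4. The labels therefore do not show whether the libraries came from separate animals. Replicate 1 had 981697 reads and replicate 2 had 1003061 reads assigned to transcript models, of which 16882 (1.72%) and 17960 (1.79%) came from ERCC spike-ins, synthetic RNAs added to the samples. The remaining 964815 and 985101 reads were the denominators of all levels in CPM, counts scaled to a total of 1000000, and 95.4% and 94.8% of them lay in annotated genes. A gene without reads was below 3.11 CPM in replicate 1 and 3.05 CPM in replicate 2, taking 3 reads as the limit that a count of 0 allows. With no second condition, the comparisons below set the replicates against each other. Apart from bootstrap intervals, named where they occur, the p-values and intervals cover counting error only. None covers the spread between animals.

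Genes of corticosteroid synthesis were among the most abundant. Cyp11a1, the mitochondrial enzyme that cleaves the cholesterol side chain in the first step of steroid synthesis (chromosome 9, 58006411 to 58027023, plus strand), reached 16882 ± 1804 CPM (SD, n = 2, as for all levels given with ±). Cyp21a1, the steroid 21-hydroxylase (chromosome 17, 34801348 to 34804561, minus strand), reached 7198 ± 759 CPM. Cyp11b1, the 11-beta-hydroxylase of the glucocorticoid-producing zona fasciculata (chromosome 15, 74834125 to 74841643, minus strand), reached 5209 ± 901 CPM. Star, which carries cholesterol into mitochondria (chromosome 8, 25806555 to 25815982, plus strand), stood at 4846 ± 225 CPM and Hsd3b1, a 3-beta-hydroxysteroid dehydrogenase (chromosome 3, 98852194 to 98859794, minus strand), at 4766 ± 33.1 CPM. The rest of the 10 highest genes were the alpha-globin Hba-a1 (7604 ± 222 CPM), the lipid carrier Apoe (6731 ± 6183 CPM, with 2359 CPM in replicate 1 and 11103 CPM in replicate 2), the respiratory chain genes Atp5b (5589 ± 293 CPM) and Cox4i1 (5216 ± 53.8 CPM) and the fatty acid binding protein Fabp4 (4317 ± 76.6 CPM). Hba-a1 has the near-identical copy Hba-a2, so the division of reads between them is uncertain.

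The splicing of the reads limited what some of these levels stand for. Single-exon reads made up 55.7% of Cyp11a1 reads in replicate 1 and 63.8% in replicate 2, and only 0.216% and 0.214% of Hsd3b1 reads lay in known models, those that match an annotated transcript. When only reads of known models were counted, with their sum as the denominator, Cyp11a1 stood at 7393 CPM and below Hba-a1 and Cyp21a1, Hsd3b1 at 14.4 CPM and Fabp4 at 1071 CPM.

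Of 18177 annotated genes with a read in either library, 14440 had at least 1 read in both. Over the 11094 genes with at least 10 reads in total, Pearson's r of log2(CPM + 1) between the replicates was 0.887 and Spearman's rho was 0.899, both across genes, which are not independent replicates. The median absolute log2 ratio was 0.36 over these genes and 0.22 over the 1894 genes with at least 200 reads. The median log2 ratio of replicate 2 over replicate 1 was -0.15, and it was 0.00 after TMM scaling, so directions of small differences depend on the scaling.

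**Figure D1:**
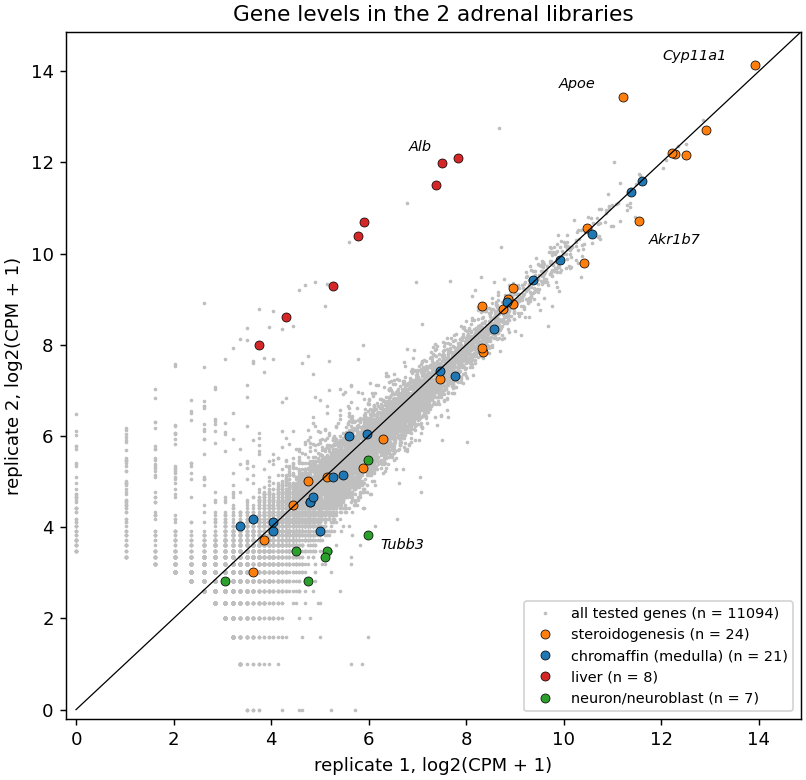
Gene levels in replicate 1 (x axis) and replicate 2 (y axis), both as log2(CPM + 1), for 11094 tested genes (grey points) and for members of the steroidogenesis (n = 24), chromaffin (n = 21), liver (n = 8) and neuron (n = 7) lists in colour, with the line of equality. The 8 liver genes lie far above the line, with Alb at 226 CPM in replicate 1 and 4392 CPM in replicate 2, while Tubb3 lies below it at 62.2 and 13.2 CPM.

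Within the steroidogenesis list, 4 of 24 genes were higher in replicate 2, 7 were higher in replicate 1 and 13 showed no difference past the threshold. Akr1b7, an aldose reductase-like enzyme of the zona fasciculata, stood at 2966 CPM in replicate 1 and 1680 CPM in replicate 2, a ratio of 0.566 (replicate 2 over replicate 1, as for all ratios, 95% interval 0.533 to 0.602; adjusted p = 8.30e-76, exact binomial test). Scarb1, the receptor that takes up lipoprotein cholesterol, had a ratio of 0.644 (0.591 to 0.702), Cyp11b1 of 0.782 (0.752 to 0.813), Cyp21a1 of 0.861 and Soat1, which esterifies cholesterol, of 0.771. On the other side, Cyp11a1 had a ratio of 1.16 (1.14 to 1.19), Mrap, an accessory protein of the ACTH receptor, of 1.22, the electron carrier Cyb5a of 1.43 and Apoe of 4.71 (4.50 to 4.93). Apoe is also made abundantly by hepatocytes, whose genes were higher in the same library. Hsd3b1, the ferredoxin Fdx1 (1464 ± 55.3 CPM) and the transcription factor Nr5a1 (435 ± 6.66 CPM) showed no difference past the threshold. The ACTH receptor Mc2r had 33 reads in each library (33.8 ± 0.498 CPM), counted on its annotated strand only, although most spliced reads at its locus were assigned to the other strand. Cyp17a1, the 17-alpha-hydroxylase, had 11 and 7 reads.

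The median log2 ratio of the steroidogenesis list was -0.08, at percentile 48.3 of 10000 random lists of the same size and expression, and 11 members passed when adjusted over the list alone. After TMM scaling the median was 0.07, with 7 genes higher in replicate 2 and 3 higher in replicate 1. Star (ratio 0.936, adjusted p = 0.0206 by the exact binomial test) changed direction and lost its call under that scaling. The calls of Cyp21a1 (adjusted p = 0.112), Soat1 (0.385) and Cyp11b2 (0.0813) were also lost there, while Hsd3b1 (9.41e-05), Fdx1 (5.01e-04) and the mitochondrial membrane protein Tspo (0.0246) became called as higher in replicate 2 (exact binomial test). Cyp11a1 changed direction when only reads of known models were counted.

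Markers of the cortical zones differed in both directions. In the zona glomerulosa list, which marks the aldosterone-producing outer zone, the aldosterone synthase Cyp11b2 (322 and 229 CPM, ratio 0.712, 0.597 to 0.847) and the endocytic adaptor Dab2 (ratio 0.681, 0.569 to 0.814) were higher in replicate 1. Of 13 genes, 11 had no difference past the threshold, among them the potassium channel Kcnk3 (1631 ± 34.9 CPM). The median log2 ratio was -0.26 (percentile 14.5), with 2 genes called when adjusted over the list alone. Cyp11b2 lost its call under TMM scaling (adjusted p = 0.0813, exact binomial test). In the zona fasciculata list, Mrap was higher in replicate 2, Cyp11b1, Akr1b7 and Scarb1 were higher in replicate 1, and 3 genes gave no call. The median was -0.03 (percentile 61.8, and 0.12 after TMM scaling), with 5 genes called when adjusted over the list alone. Akr1c18, the 20-alpha-hydroxysteroid dehydrogenase that marks the transient inner X-zone of the juvenile cortex, stood at 2084 CPM in replicate 1 and 4130 CPM in replicate 2, a ratio of 1.98 (1.88 to 2.09; adjusted p = 3.00e-144, exact binomial test). The 3 other X-zone genes had between 6 and 12 reads per library and gave no call, so the list median of 0.44 (percentile 92.8, 1 gene adjusted over the list alone) rested on few reads.

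Chromaffin cells of the medulla were represented at nearly equal levels in both libraries. The granins Chgb (3116 ± 5.95 CPM) and Chga (2629 ± 20.6 CPM), which pack the secretory granules, led the list, followed by tyrosine hydroxylase Th, the rate-limiting enzyme of catecholamine synthesis (1453 ± 115 CPM), the granin Scg2 (950 ± 24.9 CPM), Pnmt, which converts noradrenaline to adrenaline (671 ± 20.6 CPM), and neuropeptide Npy (473 ± 27.9 CPM). No member was higher in replicate 2, Th (ratio 0.894, 0.830 to 0.963) and dopamine beta-hydroxylase Dbh (0.731, 0.590 to 0.904) were higher in replicate 1. The other 19 of 21 tested members showed no difference past the threshold. The median log2 ratio was -0.05 (percentile 70.8), and 2 genes were called when adjusted over the list alone. Both calls were lost under TMM scaling, which gave a median of 0.10 and 2 genes higher in replicate 2. For Cyb561, the cytochrome of the granule membrane (352 ± 41.4 CPM), 72.6% and 71.4% of reads lay in splice forms outside the annotation, as did 85.2% and 87.5% of the 27 and 24 reads of Penk, the enkephalin precursor.

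Genes of fat and blood were abundant. Fabp4, the lipid droplet protein Cidea (3087 ± 59.9 CPM), the carbonic anhydrase Car3 (2037 ± 115 CPM) and Ucp1, the uncoupling protein of brown fat (2007 ± 82.2 CPM), headed the adipose list, which summed to 13104 ± 33.2 CPM. Its median log2 ratio was -0.03 (percentile 62.5), with the hormone Retn higher in replicate 2 (6 and 26 reads, ratio 4.24, 1.71 to 12.6), Cfd, the adipsin gene, higher in replicate 1 (ratio 0.804), 8 of 10 genes without a call and 3 called when adjusted over the list alone. The erythroid list summed to 14526 ± 70.8 CPM and had a median of 0.05 (percentile 75.4), with Hbb-bs (ratio 0.895) and the haem synthesis enzyme Alas2 (0.671) higher in replicate 1, 3 genes without a call and 3 called when adjusted over the list alone. Reads of Hbb-bs and Hbb-bt cannot be divided with certainty because the copies are near-identical. TMM scaling moved the adipose median to 0.12 with 5 genes higher in replicate 2, ended the call of Cfd (adjusted p = 0.308, exact binomial test), and ended both erythroid calls while 3 globin genes became higher in replicate 2.

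All calls in the neuron, smooth muscle, immune and capsule lists were toward replicate 1, although many members gave no call. In the neuron list, the neuronal tubulin Tubb3 (ratio 0.212, 0.107 to 0.391; adjusted p = 5.76e-07, exact binomial test), the intermediate filaments Prph (0.297) and Nefl (0.276) and the growth cone protein Gap43 (0.235) were higher in replicate 1, and 3 of 7 genes gave no call. Their reads were few, with Tubb3 at 60 and 13. The smooth muscle and pericyte list had 2 of 5 genes higher in replicate 1, the pericyte gene Rgs5 (ratio 0.454, 0.327 to 0.625) and smooth muscle actin Acta2 (0.350, 0.199 to 0.592). Among macrophage and immune genes, Cd74, the invariant chain of MHC class II (340 and 86 reads, ratio 0.248, 0.193 to 0.315; adjusted p = 1.29e-35, exact binomial test), and lysozyme Lyz2 (0.327) were higher in replicate 1. The complement genes C1qa and C1qb showed no difference past the threshold, and 6 of 8 genes gave no call. In the capsule and fibroblast list, the collagens Col3a1 (1011 ± 409 CPM, ratio 0.555) and Col1a1 (0.661) and the proteoglycan Dcn (0.707) were higher in replicate 1 and 6 of 9 genes gave no call.

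The medians of these lists were -1.70 for neurons (percentile 0, 4 genes adjusted over the list alone), -1.13 for smooth muscle (percentile 0.01, 3 genes adjusted over the list alone), -0.24 for immune genes (percentile 32.5, 3 genes adjusted over the list alone) and 0.04 for the capsule (percentile 84.1, 4 genes adjusted over the list alone). With members of fewer reads included, the neuron median was -0.92 and the immune median -0.45. The Schwann cell list had a median of -0.55 (percentile 8.58, 2 genes adjusted over the list alone), with the myelin enzyme Cnp (ratio 0.684) higher in replicate 1 and 3 of 5 without a call. The endothelial list had a median of -0.35 (percentile 9.80, 2 genes adjusted over the list alone), with the receptor Tie1 (ratio 0.538) higher in replicate 1 and 9 of 10 genes without a call. TMM scaling ended the calls of Cnp and Dcn.

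Liver transcripts set the libraries apart. All 8 liver genes were higher in replicate 2, and all 8 passed when adjusted over the list alone. Their summed level was 753 CPM in replicate 1 and 15655 CPM in replicate 2. Albumin (Alb, the main plasma protein) stood at 226 and 4392 CPM (ratio 19.4, 17.0 to 22.4), the plasma glycoprotein Ahsg at 180 and 4087 CPM (22.7, 19.5 to 26.5), the high-density lipoprotein gene Apoa1 at 166 and 2921 CPM (17.6, 15.0 to 20.8), Apoa2 at 59.1 and 1651 CPM (27.9) and the thyroid hormone carrier Ttr at 53.9 and 1337 CPM (24.8). The ratios of the fibrinogen chains Fgb and Fga were 16.8 and 20.9 (adjusted p = 4.62e-132 and 2.27e-86, exact binomial test), and that of the protease inhibitor Serpina1a, which has near-identical copies, was 20.3. The list median was 4.32 on the log2 scale, above every random list (percentile 100), and 4.47 after TMM scaling. In contrast, kidney genes were at the limit of detection: 9 of 10 had no reads in either library, which allows up to 3.11 and 3.05 CPM, Aqp2 had 2 and 4 reads, and no member could be tested, so 0 were called when adjusted over the list alone.

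Across all tested genes, 1017 of 11094 (9.17%) differed between the libraries, 483 higher in replicate 2 and 534 higher in replicate 1 (two-sided exact binomial test, Benjamini-Hochberg adjusted p under 0.05). Among them 504 differed at least 2-fold, 326 higher in replicate 2 and 178 higher in replicate 1, and 155 were at least 10-fold higher in replicate 2 against 15 in replicate 1. TMM scaling called 872 genes, of which 76.2% were higher in replicate 2 against 47.5% in the main scaling.

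Several of the 10 genes with the largest ratios toward replicate 2, ranked with 0.5 reads added to each library, are known from hepatocytes. Fabp1, the liver fatty acid binding protein, had 5 and 475 reads (ratio 93.0, 39.6 to 288), Cyp2c70, a bile acid hydroxylase, 2 and 128 reads (62.7, 17.0 to 523), the sulfotransferase Sult2a1, which has close paralogs, 3 and 187 reads (61.1, 20.6 to 299) and the apolipoprotein Apoc3 3 and 182 reads (59.4, 20.0 to 291). A further 6 genes had no reads in replicate 1: Gm45233 (at least 28.4-fold higher), Azgp1 (at least 21.9-fold), the phosphoprotein Spp2 (at least 20.6-fold), the asialoglycoprotein receptor Asgr1 and Akr1c6 (at least 17.3-fold each) and the deacetylase Aadac (at least 16.7-fold).

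The largest ratios toward replicate 1, ranked likewise, belonged to genes of varied function. The mucin-like Glycam1, a ligand made by lymph node venules, had 55 reads in replicate 1 and 1 in replicate 2 (56.2-fold higher in replicate 1, ratio interval 4.43e-04 to 0.103), and the chemokine Ccl21a, which attracts lymphocytes, had 60 and 2 (30.6-fold, 0.00387 to 0.123). The MHC class II genes H2-Eb1 (5.33-fold), H2-Ab1 (5.07-fold) and H2-Aa (5.01-fold), members of a variable gene family, followed with Tubb3 (4.71-fold), Cyp2b10 (4.56-fold) and the processed pseudogene Gm9755 (6.0-fold), whose reads can be shared with its parent gene. The antisense gene Gm26724 had 50 reads and 0 (at least 17.0-fold).

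All calls among immediate early and stress genes and among mitochondrially encoded genes were toward replicate 2, the library with the higher liver genes. Of 12 immediate early and stress genes, 6 were higher in replicate 2, among them the transcription factors Junb (ratio 3.36, 2.86 to 3.96; adjusted p = 1.24e-56, exact binomial test), Fos (4.35, 2.08 to 10.2), Nr4a2 (3.07) and Nr4a1 (1.46), and the near-identical heat shock genes Hspa1a (3.86) and Hspa1b (2.79). The other 6, including Ier2 (178 ± 30.0 CPM), gave no call. The median log2 ratio was 0.44 (percentile 99.99), with 7 genes called when adjusted over the list alone. Of 11 mitochondrially encoded genes, 9 were higher in replicate 2, with cytochrome b (mt-Cytb) at 316 and 714 CPM (ratio 2.26, 1.97 to 2.59; adjusted p = 8.17e-33, exact binomial test) and the oxidase subunit mt-Co1 at 893 and 1138 CPM (1.27). The median was 1.08 (percentile 100), and 10 passed when adjusted over the list alone.

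Smaller shifts toward replicate 2, the library with the higher liver genes, appeared in 3 further lists. The cholesterol synthesis list had a median of 0.20 (percentile 99.9): Fdps (ratio 1.89, 1.41 to 2.56), Ebp (2.00) and Sc5d (2.66) were higher in replicate 2, Dhcr7 (0.780) was higher in replicate 1 and 16 of 20 gave no call. Of the list, 4 were called when adjusted over the list alone. Few Dhcr7 reads lay in known models, which alone gave 2.13 CPM in place of 409 CPM, and its call was lost under TMM scaling. The imprinted list had a median of 0.17 (percentile 99.0), with the growth-related transcripts H19 (ratio 3.63, 2.47 to 5.47), Igf2 (0 and 11 reads, at least 3.59-fold) and Cdkn1c (1.24) higher in replicate 2, Gnas (0.841, no call under TMM scaling) higher in replicate 1. In this list 13 of 17 had no call and 4 were called when adjusted over the list alone. The cell cycle list had a median of 0.38 (percentile 99.98), yet none of its 13 genes was called over all genes by the exact binomial test and 0 when adjusted over the list alone (1 under TMM scaling), with the replication gene Mcm2 at 133 ± 8.93 CPM.

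The Y-linked genes Eif2s3y (69.3 ± 6.10 CPM), Ddx3y (67.2 ± 3.17 CPM) and Uty (23.2 ± 9.77 CPM) were present in both libraries and Xist, the RNA of X inactivation in females, had 0 reads in either. The 3 tested sex chromosome genes had a median of -0.18 (percentile 48.0) and gave 0 calls over all genes and 0 when adjusted over the list alone. Of 21 lists with at least 3 tested genes, 8 had medians outside the central 95% of random lists, 6 above and 2 below. The random lists were matched on expression but not on transcript length, with which ratios also changed (below). Small list shifts were therefore not set apart from that trend.

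**Figure D2:**
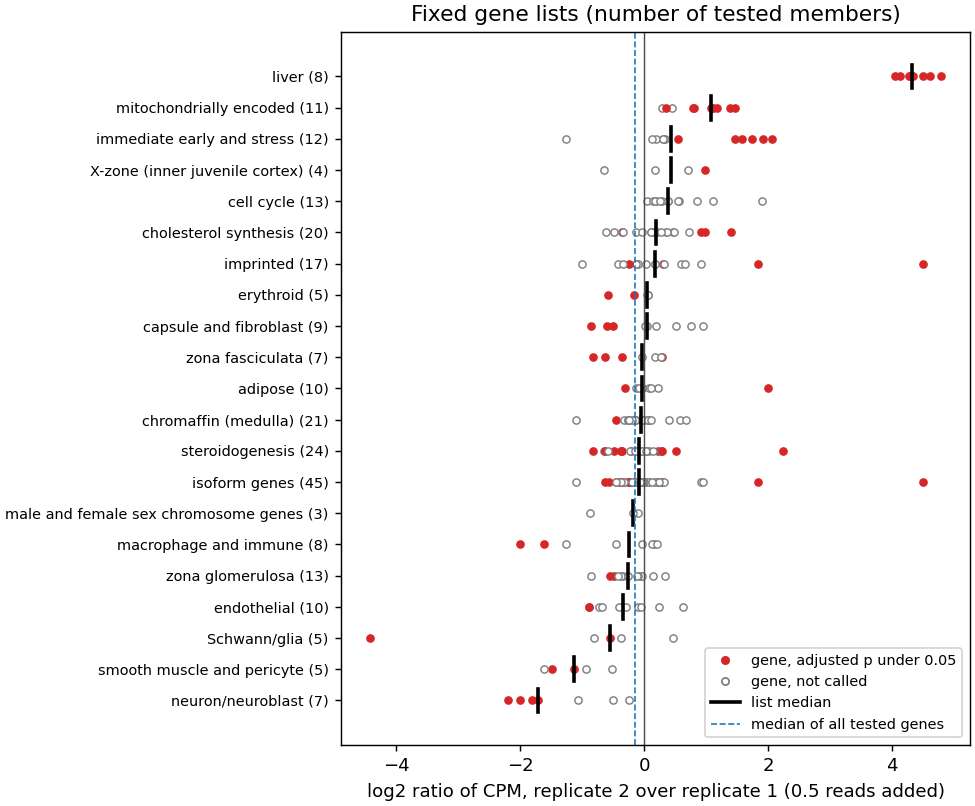
Log2 ratio of CPM, replicate 2 over replicate 1, with 0.5 reads added to each library (x axis), for each tested gene (points, red where adjusted p was under 0.05) of 21 fixed lists (y axis, number of tested genes in brackets), with list medians as black bars and the median of all tested genes (-0.15) as a dashed line. The liver list has the highest median (4.32) and the neuron list the lowest (-1.70), and TMM scaling moves the medians of the steroidogenesis, zona fasciculata, chromaffin, adipose and isoform lists from just below 0 to just above it.

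The ERCC spike-ins gave a comparison for the steps that they shared with the adrenal RNA. Of 31 spike-ins tested, 0 were called by the same exact binomial test and 3 had an unadjusted p under 0.05. Pearson's r was 0.969, and the median absolute log2 ratio was 0.05 over the 11 spike-ins with at least 200 reads. A chi-square test of their counts gave 47.1 on 30 degrees of freedom (p = 0.0242, across spike-ins).

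Gene ratios changed with transcript length. Over 10567 genes, Spearman's rho of the log2 ratio with annotated length was -0.23, across genes. The median ratio ran from 0.18 for 210 genes of up to 500 bases to -0.26 for 2308 genes of over 4000 bases, and TMM scaling moved these to 0.34 and -0.11. The mean annotated length weighted by reads was 2190 bases in replicate 1 and 2033 bases in replicate 2.

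**Figure D3:**
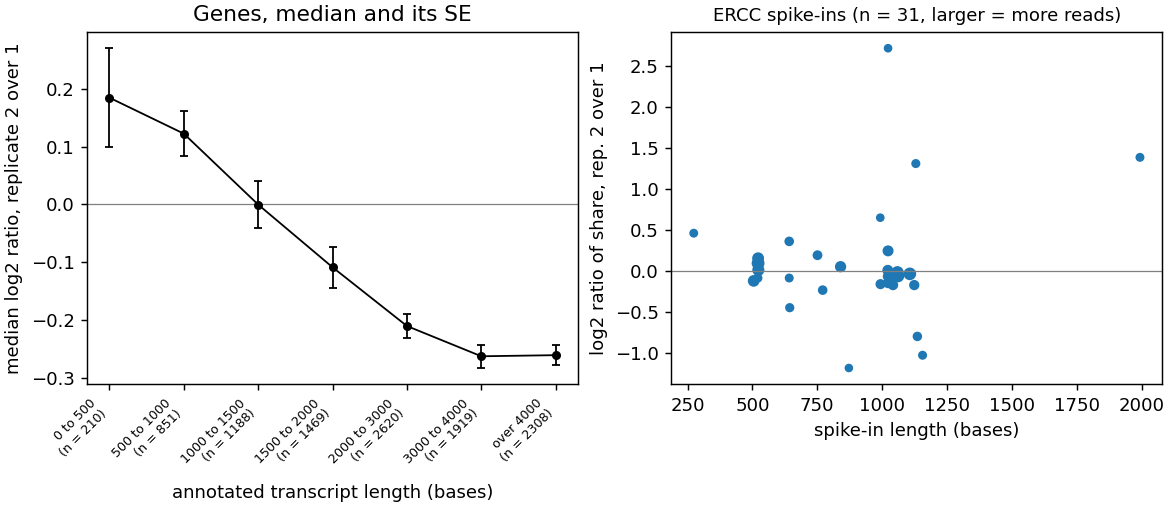
Left, median log2 ratio of replicate 2 over replicate 1 (y axis) of genes in bins of annotated length (x axis, number of genes in brackets), with the standard error of the median, falling from 0.18 to -0.26. Right, log2 ratio of each of 31 ERCC spike-ins (share of spike-in reads, y axis) against its length from 274 to 1994 bases (x axis), with larger points for more reads.

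Reads of known models, spliced or single-exon, made up 71.4% ± 2.11 of reads (SD, n = 2, as for all shares given with ±). Truncated forms of annotated transcripts (incomplete splice matches) took 11.2% ± 1.76, genomic models, mostly unspliced, 5.88% ± 0.600, antisense models 3.97% ± 0.373 and intergenic models 0.730% ± 0.0930. New combinations of annotated splice sites took 3.92% ± 0.535 and chains with an unannotated splice site 2.96% ± 0.182, together 7.39% of reads in replicate 1 (Wilson 95% interval 7.34 to 7.44) and 6.37% in replicate 2 (6.33 to 6.42). Classes could differ between the tables: the most abundant single-exon model of Cyp11a1 was genomic in replicate 1 (8386 reads) and truncated, with another start, in replicate 2 (11405 reads). Of 20103 shared intron chains outside known models, truncated ones included, 1350 (6.72%) carried different classes.

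Most unannotated splice chains with more than a single read recurred. Of 7945 such chains with at least 2 reads in replicate 1, 65.4% (64.4 to 66.5) were also found in replicate 2, and of 6845 in replicate 2, 70.4% (69.3 to 71.5) were found in replicate 1, matched by exact coordinates. The share was 27.0% with at least 1 read and 95.6% with at least 5 reads.

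The most abundant of these chains belonged to Oaz1, an antizyme that limits polyamine synthesis (1544 ± 171 CPM), and held 94.6% and 94.7% of its reads. It differed from the nearest annotated transcript only in lacking an annotated intron of 4 bases on chromosome 10, 80828292 to 80828295. The related antizyme Oaz2 (254 ± 18.3 CPM) likewise lacked an annotated 4-base intron on chromosome 9, 65686269 to 65686272. Translation of antizymes is known to involve a shift of the reading frame. The annotation holds 353 introns of under 20 bases in 257 genes. Mrpl33, a mitochondrial ribosomal protein (361 ± 68.7 CPM), used an unannotated intron on chromosome 5, 31614031 to 31616380, in 94.4% and 91.8% of its reads. Idh3g, a subunit of isocitrate dehydrogenase (349 ± 25.4 CPM), used an unannotated intron on chromosome X, 73782104 to 73782670, in 76.5% and 74.3%. Phb2, an inner membrane prohibitin (328 ± 43.3 CPM), joined annotated splice sites across 124716031 to 124716605 on chromosome 6 in place of a pair of annotated introns. The transcriptional corepressor Ctbp1 (245 ± 60.9 CPM), the kinase Mknk2 (235 ± 15.1 CPM), the RNA-binding protein Hnrnpk (204 ± 57.4 CPM) and Cdkn1c (199 ± 29.0 CPM) completed the named chains in known genes. The remaining chain, with 172 and 231 reads, followed the introns of Mc2r (chromosome 18, 68408317 to 68429211) on the opposite strand.

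Many genes expressed more than 1 isoform. Of 5155 genes with at least 20 full-splice reads in each library, 1250 (24.2%) had a second transcript of at least 10% in both libraries, and 2139 (41.5%) had a top transcript of at least 90% in both. Among 39 genes of the isoform list with enough reads, 13 had such a second transcript and 15 had a top transcript of at least 90%, such as Star-201 with 98.3% and 98.2% and Chgb-201 with 99.2% and 98.6%. Gnas, the stimulatory G protein gene, was led by Gnas-208 with 56.4% ± 3.71, followed by Gnas-207 with 20.4% ± 1.2, which joins 174334285 to 174341649 on chromosome 2 as a single intron where the first uses a pair of introns. Pkm, the glycolytic pyruvate kinase, was led by Pkm-201 with 75.9% ± 3.18, whose introns are 59672074 to 59675567 and 59675735 to 59678043 on chromosome 9, against 16.6% ± 1.43 for Pkm-202, which uses the alternative, mutually exclusive exon upstream. The myosin light chain Myl6 divided into 49.9% ± 2.65 for Myl6-201 and 38.8% ± 0.472 for Myl6-206, and the complex I gene Ndufv3 into 66.1% ± 7.22 for Ndufv3-202 and 31.8% ± 6.14 for Ndufv3-201.

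The notch ligand-like Dlk1 (top transcript 70.2% ± 0.364), the splicing factor Hnrnpa2b1 (53.0% ± 1.78), the angiogenic factor Vegfa (32.7% ± 1.89), the amyloid precursor App (37.6% ± 1.82), the translation factor Eif4a2 (59.2% ± 6.09) and the ribosomal gene Rps24 (42.4% ± 4.46) also had a second transcript of at least 10%. The top form of Cd47, an inhibitory signal to macrophages, was a chain outside the annotation with 58.2% ± 1.55, joining 49868113 to 49884164 on chromosome 16 in a single intron. For Hsd3b1 the top form, with 36.7% ± 3.28, rested on 25 and 21 full-splice reads and was also unannotated, because a 4-exon truncated model held 71.1% and 67.8% of all its reads and was not counted. Counting truncated models as transcripts lowered the share of the same form to 0.599% for Hsd3b1, 19.9% for Hnrnpa2b1 and 26.9% for Rps24.

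Isoform shares rarely differed between the libraries. Of 4817 genes tested, 6 differed (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05) and 230 had an unadjusted p under 0.05. The top transcript of Hsd11b1, which regenerates active glucocorticoid, took 19.2% in replicate 1 (Wilson interval 8.51 to 37.9) and 72.7% in replicate 2 (61.0 to 82.0; adjusted p = 0.0147, exact test). Adenosine kinase Adk went from 38.1% (30.3 to 46.5) to 64.3% (56.8 to 71.1; adjusted p = 0.0147, exact test), and the tyrosine catabolism enzyme Gstz1 from 28.2% (19.8 to 38.6) to 57.3% (48.2 to 65.9; adjusted p = 0.0439, exact test). The shares were higher in replicate 1 for Col18a1, a basement membrane collagen (57.8% and 16.7%; adjusted p = 0.0262, exact test), and for Acsl5, an acyl-CoA synthetase (93.4% and 65.6%; adjusted p = 0.0148, exact test). The sixth gene, Atp5b, named after its values were seen, had 99.0% and 97.7% (adjusted p = 0.0439, exact test). Hsd11b1, Adk, Gstz1 and Acsl5 are also expressed by hepatocytes, whose genes were higher in replicate 2.

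No gene of the isoform list differed over all genes tested by Fisher's exact test, and 4 did when adjusted over the list alone. In expression, the isoform list had 4 genes higher in replicate 2, 11 higher in replicate 1 and 30 without a call, with a median log2 ratio of -0.09 (percentile 47.0, and 0.07 after TMM scaling) and 19 genes called when adjusted over the list alone. Counting truncated models as transcripts raised the number of genes with differing shares to 21.

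**Figure D4:**
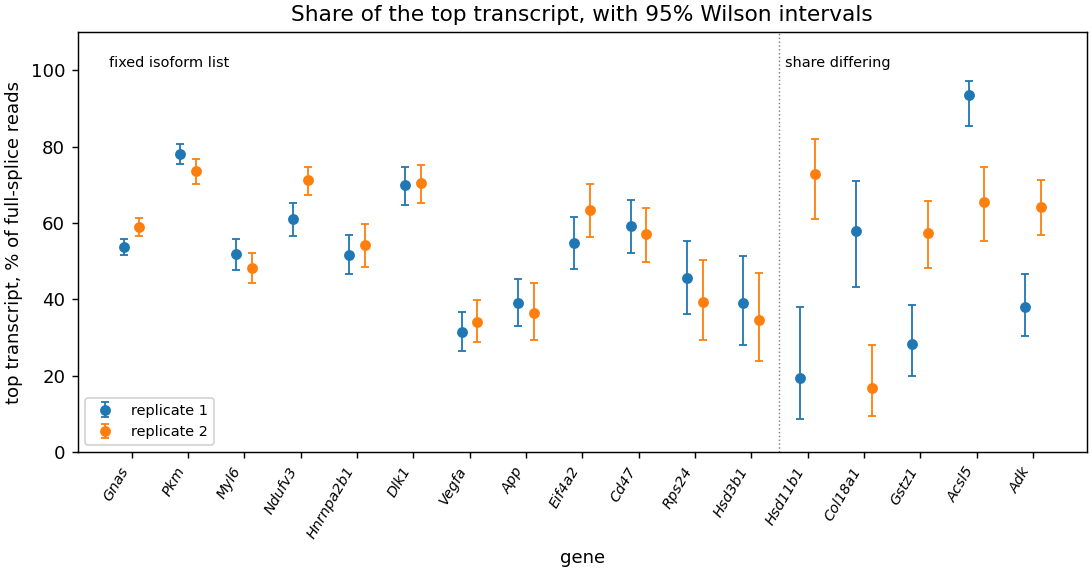
Share of full-splice reads taken by the top transcript (y axis, percent, with 95% Wilson intervals) in replicate 1 and replicate 2 for 12 genes of the fixed isoform list and 5 of the 6 genes whose shares differed (x axis). Hsd11b1 has the largest difference, from 19.2% to 72.7%.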

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

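The tests in this part were chosen only after the patterns had been seen, and no biological explanation was tested because the labels give a single group.

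Spliced chains outside annotated genes entered no comparison, and 52 of them had more than 3 reads in each library, above the limit that a count of 0 allows. Of these, 19 had introns that are all annotated on the opposite strand of a known gene and 33 did not. The most abundant without annotated introns, named after their values were seen, lay on chromosome X, 32503517 to 32504259 (74 and 21 reads), and on chromosome Y, 43919008 to 43919084 (51 and 34 reads). Introns of the ubiquitin-like gene Ubl3 (49 and 61 reads) and of the splicing regulator Mbnl1 (37 and 37 reads) were among those seen on the opposite strand, also chosen after their values were seen.

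The intron chain of Mc2r, the ACTH receptor, was seen on the opposite strand in 172 reads of replicate 1 and 231 reads of replicate 2. Together with shorter chains, 176 and 232 opposite-strand reads used Mc2r introns only, against 24 and 27 spliced reads assigned to Mc2r, which makes 88.0% (Wilson interval 82.8 to 91.8) and 89.6% (85.3 to 92.7) of both kinds added up. A general rate of wrong strand calls is argued against by the other genes with at least 100 such reads, of which 0.0389% lay on the opposite strand, and Mc2r was the only gene of 3197 with over 50% when both libraries were added up. A separate gene on the plus strand and a strand error specific to this locus, such as one set by its splice site sequences, stay open and were not tested, the latter because no genome sequence was used here. Until this is settled, the 33 reads per library counted for Mc2r may understate its level.

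Liver transcripts were about 20-fold higher in replicate 2. A difference in scaling moves all log2 ratios by the same shift. It is argued against because the median was 4.32 for the liver list and -0.15 over all tested genes. The liver median of 4.47 after TMM scaling adds nothing, since that shift could not have brought it near 0. Another tissue in place of the adrenal is argued against by the steroidogenesis list, whose median was -0.0806. Liver RNA in the material of replicate 2 stays open. A list of 73 hepatocyte genes was written after the pattern was seen. It left out the fixed liver list and the 10 genes named for their ratios toward replicate 2. Its 63 tested genes had a median of 4.10, with 55 higher in replicate 2 and 1 higher in replicate 1. Only 26 stood at 10 CPM or more in replicate 1. Genes with few reads there could enter the test only through their reads in replicate 2, which can raise this median. Both lists took 0.316% of reads in replicate 1 and 3.75% in replicate 2, and held 56 of the 155 genes called at least 10-fold higher in replicate 2. If liver RNA entered, these data do not show whether it did so at dissection or later.

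Longer genes were lower in replicate 2. Liver RNA is argued against as the whole cause, since Spearman's rho with length was -0.22 (-0.23 before) without 271 genes that were liver or hepatocyte genes or at least 4-fold higher in replicate 2. Loss of long molecules in steps shared with the spike-ins cannot be told apart from no loss. The log2 ratio of spike-ins of over 1000 bases less that of spike-ins of up to 650 bases was -0.11 (-0.17 to 0.02). For genes of over 1000 and up to 2000 bases less those of up to 650 it was -0.23 (-0.29 to -0.17). Both are bootstrap intervals from 2000 draws with replacement of the spike-ins (17 short, 21 long) or the genes (405 short, 2657 long). The spike-in value came from summed reads and the gene value from medians over genes, so -0.11 and -0.23 are not on the same measure. In replicates 1 and 2, the short genes summed to 70169 and 82413 reads and the long genes to 292093 and 315863. Short spike-ins summed to 6137 and 6843 reads and long spike-ins to 10416 and 10765. On summed reads, the long class rose less than the short class, by a similar proportion in genes and in spike-ins. No interval was computed for the summed gene reads and that of the spike-ins includes 0, so the question is not decided. More truncated molecules in replicate 2 stay open. Among 1666 genes, the truncated share was higher there in 77.7% (75.6 to 79.7) of those whose share changed. Pooled over all 1666, it was 14.7% of reads in replicate 1 and 18.5% in replicate 2. Unannotated single-exon models of these genes, genomic ones included, also counted as truncated here, so more unspliced reads would raise this share too. A truncated read still counts toward its gene, so truncation may accompany the length trend without producing it.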

How the results depend on the processing

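The scaling without liver and hepatocyte genes and the classes as deposited were chosen only after the data had been seen, and the other alternatives were planned. The number of genes detected in both libraries stayed within 1.5 times (10179 with at least 5 reads, 11591 with known models only). So did the number of genes differing (760 to 1006 over 6 alternatives, 901 when scaled to reads outside liver and hepatocyte genes, and 691 of the 872 called under TMM scaling shared with the 1017). With no filter, 8 lists again lay outside the central 95% of random lists, a number that TMM and median-of-ratios scaling cannot change because they shift all lists alike. Pearson's r between the libraries was 0.917 with no filter, 0.845 with log2(CPM + 0.1), 0.919 with log2(CPM + 5) and 0.881 with known models only, against 0.887. The share of unannotated splice chains was 32.2% of models in place of 6.88% of reads and 8.27% of multi-exon reads. The share of these chains seen in both libraries was 27.0% with at least 1 read, 95.6% with at least 5 and 98.8% with at least 10, against 67.9%. Genes with a second isoform numbered 590 with at least 50 full-splice reads and 585 with a second transcript of at least 20%, where fewer genes can pass, and 1679 to 1900 when either library alone decided, against 1250. Genes with differing isoform shares numbered 21 with truncated models counted and 12 with classes as deposited, against 6. The cause was not tested for the other moves.

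The log2 ratio of Star was 0.0591 under TMM and 0.0612 under median-of-ratios scaling against -0.09, and that of Atp5b was 0.0470 and 0.0491 against -0.11, as all ratios move by the same shift there. That of Cyp11a1 was -0.0354 with known models only against 0.22. Its single-exon reads, 8392 in replicate 1 and 11410 in replicate 2, are left out there, while its known model of 9 exons had 5259 and 5024 reads. None of these reversed ratios was past the threshold. Of 87 ratios, 13 beside Star and Atp5b were no longer past it under TMM scaling, 6 beside Cyp11a1 with known models only and 6 with no filter. Scaled to reads outside liver and hepatocyte genes, 8 were no longer past it, Star and Atp5b among them. Of 115 levels, 72 moved by more than 1 SD with known models only, 47 higher and 25 lower, and 21 fell by over 1.5 times. The denominator there is the smaller sum of known-model reads, which by itself raises genes whose reads nearly all lie in known models. Of 17 top transcript shares, 9 moved when truncated models were counted. With n = 2, a level from either replicate always lies within 1 SD of the mean, so leaving a replicate out says nothing on stability. No paired analysis was possible because the series has 1 group. Depth limited the tests, which recovered 20.5% of 1.5-fold and 63.0% of 2-fold changes in simulated data, for genes of at least 50 reads. Recovery was not measured for tested genes of fewer reads, and genes of under 10 reads were not tested.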

Other observations

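Protein-coding genes took 92.4% ± 0.562 of reads (SD, n = 2), processed pseudogenes 1.40% ± 0.0417 and long intergenic noncoding RNAs 0.298% ± 0.0293. Among noncoding genes, chosen after their values were seen, Ndufb1-ps stood at 475 ± 102.5 CPM and was higher in replicate 2 (ratio 1.36, 1.19 to 1.55), and Neat1, the scaffold RNA of nuclear paraspeckles, stood at 250 ± 13.1 CPM with no difference past the threshold (ratio 0.929, 0.774 to 1.11). Neat1 kept its lack of a call under TMM scaling, and Ndufb1-ps kept its call.

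For some genes nearly all reads lay outside known models, those that match an annotated transcript. With known models only, the mean level of the ubiquitin hydrolase Uchl1 was 3.56 CPM in place of 52.9 CPM, that of the vesicular transporter Slc18a1 was 0 in place of 14.3 CPM and that of the collagen Col1a2 was 0 in place of 93.8 CPM. Opposite-strand shares of over 5% were seen in 9 of 3197 genes, with the orphan receptor Nr2f2 at 50.7% (39.3 to 62.0) in replicate 1 and 37.7% (25.9 to 51.2) in replicate 2, chosen after its values were seen. Most truncated reads were the 3' part of a known transcript, 71.3% of them in replicate 1 and 63.4% in replicate 2. The latter share is lowered by 11405 single-exon Cyp11a1 reads classed as truncated, without a 3' label, in replicate 2. In replicate 1 the most abundant single-exon model of that gene (8386 reads) was classed as genomic.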
